A study of Mus musculus with 81 samples.

How the data were processed

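Messenger RNA of sorted mouse macrophages and progenitors was measured on Affymetrix arrays, 81 in all, from wild-type and Irf8 knockout mice at E8, E9.5, E14 and 6 weeks of age. Per the labels' protocols, tissues were digested with collagenase or dispase, with a Percoll step for brain, and cells were sorted by FACS. RNA was isolated with PicoPure columns, amplified with Ovation PicoSL WTA V2 and labelled with the Encore Biotin Module. The deposited values were log2 signals that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. The versions of both and the genome build are not given in the sources used here. Scanner files were not used here.

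The value table held 41345 probes, of which 25335 were in the probe table and 16010 were not. Of those in the table, 23521 had 1 gene symbol, 1814 had several and 0 had none, and only the first kind was used. For 23328 of them the gene ID matched the reference table, and 0 symbols were updated. Of the 22180 genes, 1082 had more than 1 probe, and the probe with the highest mean over all arrays was kept. A gene was tested when its value exceeded 3.041, the 50th percentile of the whole table, in at least 2 arrays, which left 17099 genes. The array medians ran from 2.942 to 3.195 log2, and no further normalization was applied. The deposited replicate 2 of the A2 knockout had 2 array runs, which were averaged and counted as 1 sample.

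Groups were population, stage and genotype as the labels give them, 27 groups with 80 samples. A mean per group was fitted to all samples with limma 3.58.1 in R 4.3.3, with moderated t statistics and a trend of variance on intensity, 53 residual degrees of freedom and a median of 9.09 prior degrees of freedom. All samples were fitted together because groups of 2 or 3 give a poor estimate of the spread on their own. Comparisons were knockout against wild type in 13 populations, steps of development, adult tissues against each other, the gates within an organ, 4 differences of knockout effects and a moderated F-test over the 4 adult resident populations. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. P-values and standard errors use the spread between samples pooled over all groups, and the labels do not say which came from separate animals.

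Gene lists, 32 with 688 entries of which 617 were tested, were written before the files were seen, from general knowledge of the cell types. They were tested with camera of limma, with a preset inter-gene correlation of 0.01, and again with an estimated correlation. Members were counted over all genes and adjusted over the list alone. Genes named in the text were Irf8, the 8 largest rises and 8 largest falls per comparison among called genes whose replicates did not overlap, up to 4 members per list with the smallest adjusted p, and 3 per direction for differences of effects. A gene named in 1 comparison could be given in others. Genes called in 3 or more adult comparisons were counted against 1000 shuffles of the gene labels.

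The code was tested on simulated data made from the fitted spread. With 3 samples against 3, 52% of genes shifted by 1 log2 unit and 96% of those shifted by 2 were called, with 8 false calls, and with 3 against 2 the shares were 42% and 90%, with 2 false calls. A list shifted by 1 log2 unit was found (camera adjusted p = 3.14e-36), and 0 of 31 other lists were called. This checks the code, not calls on real lists, such as neutrophil markers with an estimated correlation of 0.388.

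Alternatives fixed beforehand were array weights, a fit of only the compared groups, the replicate number as a block, quantile normalization, median centring, no floor, a floor at the 75th percentile, every probe on its own, each array run of the repeated sample, each sample left out in turn, an estimated correlation and fry. A run without genes on chromosomes X and Y was added after the sex-linked genes were seen. Other splits of the compared samples were fitted, all 10 for 3 against 3 and 100 drawn otherwise. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The samples, comparisons, tests, lists and alternatives were chosen before the data were examined, other than the additions named here and in the closing part.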

Results

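Gene expression was measured on arrays in sorted mouse macrophage and progenitor populations of wild-type mice and of mice with a knockout of Irf8, a transcription factor of the interferon regulatory factor family. The 81 arrays gave 80 samples in 27 groups, 14 wild type with 41 samples and 13 knockout with 39 samples. Groups held 3 samples, except the wild-type E14 kidney F4/80high macrophages with 2. Populations were E8 erythro-myeloid progenitors (wild type), the yolk-sac populations labelled A1 and A2 at E9.5, and at E14 and in adults of 6 weeks microglia, Kupffer cells of the liver, kidney F4/80high macrophages and CD11bhigh macrophages of liver and kidney, with adult Langerhans cells of the skin. Array medians lay between 2.94 and 3.20 log2 units, and 17099 genes were tested. Values in brackets after a gene are log2 changes ± standard error of the limma fit, all past the adjusted p threshold of 0.05, and the number of arrays limits the precision.

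Irf8 was read first, because the knockout targets it, and its levels are given as log2 mean ± SD of each group. Its level was clearly lower in the knockout in E14 liver CD11bhigh macrophages, at 5.72 ± 0.64 against 8.74 ± 0.12 in the wild type. It was also called lower in Langerhans cells, at 7.72 ± 0.42 against 8.81 ± 0.17 in the wild type. So it was in adult liver CD11bhigh macrophages, at 8.76 ± 0.21 against 9.45 ± 0.08. In adult kidney CD11bhigh macrophages it was called lower, at 8.25 ± 0.50 against 9.01 ± 0.49, with overlapping samples. The limma log2 changes were -3.02 ± 0.25 (adjusted p = 5.65e-15), -1.09 ± 0.25 (adjusted p = 0.000413), -0.69 ± 0.25 (adjusted p = 0.0465) and -0.76 ± 0.25 (adjusted p = 0.0312), in that order. In 5 further populations the knockout mean was below the wild-type mean without passing the test, namely adult Kupffer cells, at 8.46 ± 0.40 against 9.09 ± 0.29 in the wild type, E14 Kupffer cells, at 8.42 ± 0.32 against 8.65 ± 0.11 in the wild type, E14 kidney CD11bhigh macrophages, at 8.57 ± 0.01 against 8.90 ± 0.13 in the wild type, E14 microglia, at 9.25 ± 0.26 against 9.36 ± 0.23 in the wild type, and A1, at 6.61 ± 0.63 against 6.70 ± 0.40 in the wild type. The knockout mean was not below the wild-type mean in adult microglia, at 10.30 ± 0.34 against 9.83 ± 0.13. The same held in adult kidney F4/80high macrophages, at 9.76 ± 0.15 against 9.60 ± 0.05. It held in those of E14, at 9.28 ± 0.18 against 8.98 ± 0.00, and in A2, at 8.94 ± 0.35 against 8.68 ± 0.09. E8 progenitors had 3.03 ± 0.46 (SD, n = 3). Which part of the gene the array reads and which part was deleted is not given in the sources used here, so the level does not check the genotype labels.

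**Figure D1:**
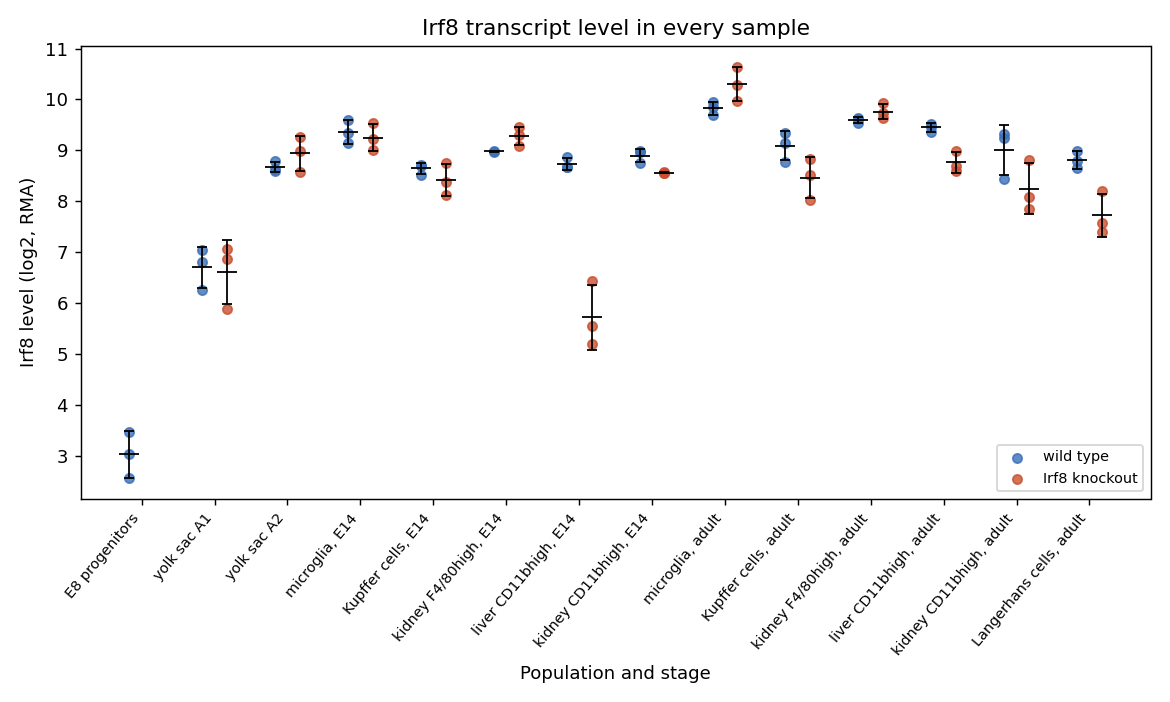
Irf8 level (log2) of every sample by population and stage, wild type in blue and knockout in red, with the group mean as a bar and the SD as whiskers. The knockout samples of E14 liver CD11bhigh macrophages lie between 5.19 and 6.43, below all wild-type samples of that population.

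In adult microglia, the macrophages of the brain, the knockout changed 2490 genes, 1001 higher and 1489 lower (3 samples against 3). The apolipoprotein gene Apoc1 (7.91 ± 0.25) showed the largest rise, followed by Pf4 (7.43 ± 0.58), Ms4a7 (7.18 ± 0.36) and Cxcl2 (6.60 ± 0.34). Sall1 (-6.84 ± 0.34), a transcription factor typical of microglia, fell, as did Upk1b (-6.66 ± 0.26), Ly86 (-6.61 ± 0.62), Adgrg1 (-5.38 ± 0.50) and Il7r (-5.35 ± 0.44). 1 of 22 tested microglia signature genes was higher, 10 lower and 11 not past the test (adjusted over the list alone 2 and 11, camera adjusted p = 1.21e-07). Slc2a5 (-4.06 ± 0.40) and Crybb1 (-2.39 ± 0.29) were among them. Of 34 tested interferon-stimulated genes, 20 were higher, 2 lower and 12 not past the test (adjusted over the list alone 23 and 2, camera adjusted p = 5.42e-12, adjusted p = 0.108 with an estimated correlation). Oas2 (4.76 ± 0.30), Rtp4 (2.61 ± 0.26) and Ifi204 (3.44 ± 0.43) were among them. MHC class II genes (12 tested) counted 0 higher, 6 lower and 6 not past the test (adjusted over the list alone 0 and 6, camera adjusted p = 0.0034, adjusted p = 0.246 with an estimated correlation). H2-DMa (-3.10 ± 0.27) and H2-Ob (-1.82 ± 0.37) were among them. 0 of 26 tested cell cycle genes were higher, 10 lower and 16 not past the test (adjusted over the list alone 0 and 12, camera adjusted p = 6.53e-05, adjusted p = 0.246 with an estimated correlation). Mcm3 (-1.60 ± 0.16) and Nusap1 (-1.05 ± 0.23) were among them. Of 24 tested neutrophil markers, 3 were higher, 0 lower and 21 not past the test (adjusted over the list alone 7 and 0, camera adjusted p = 0.0105, adjusted p = 0.639 with an estimated correlation). The neutrophil list means were 3.21, 5.64 and 3.75 in wild type and 4.44, 5.58 and 5.02 in the knockout, so wild-type replicate 2 lay above every knockout sample, and the camera call was lost without wild-type replicate 1 (adjusted p = 0.179) or 3 (0.0839) or knockout replicate 2 (0.127). All knockout samples and wild-type replicates 2 and 3 had high Xist, while wild-type replicate 1 had Xist at 2.99 and the Y-linked Eif2s3y at 7.74.

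In adult Kupffer cells, the macrophages of the liver sinusoids, 768 genes were higher and 1264 lower in the knockout (2032 in all, 3 samples against 3). The interferon-inducible GTPase gene Gbp2b (-5.84 ± 0.36) fell the furthest, with Tlr12 (-4.59 ± 0.32) and Klra2 (-4.31 ± 0.46). Genes of endothelial cells rose, among them the growth factor receptor gene Kdr (2.87 ± 0.34), Clec14a (2.89 ± 0.32) and F8 (2.84 ± 0.34). Endothelial markers (18 tested) counted 16 higher, 0 lower and 2 not past the test (adjusted over the list alone 17 and 0, camera adjusted p = 1.35e-24). Sox18 (2.45 ± 0.32) and Stab2 (1.83 ± 0.26) were among them. The endothelial list means were 5.15, 5.11 and 6.57 in wild-type replicates 1, 2 and 3, so replicate 3 stood apart, and 7.19, 7.67 and 7.18 in the knockout. 6 of 13 tested B cell markers were higher, 0 lower and 7 not past the test (adjusted over the list alone 8 and 0, camera adjusted p = 1.22e-06). Of 22 tested Kupffer cell signature genes, 0 were higher, 4 lower and 18 not past the test (adjusted over the list alone 0 and 6, camera adjusted p = 0.0057, adjusted p = 0.236 with an estimated correlation). Cd163 (-2.40 ± 0.44) and Kcna2 (-1.39 ± 0.34) were among them. Pattern recognition receptors (28 tested) counted 0 higher, 14 lower and 14 not past the test (adjusted over the list alone 0 and 16, camera adjusted p = 1.43e-10). Cd180 (-1.90 ± 0.21), Tlr9 (-2.20 ± 0.30) and Tlr6 (-1.95 ± 0.31) were among them. 0 of 12 tested MHC class II genes were higher, 7 lower and 5 not past the test (adjusted over the list alone 0 and 8, camera adjusted p = 0.00101, adjusted p = 0.236 with an estimated correlation). H2-Aa (-2.05 ± 0.36) and H2-Eb1 (-1.83 ± 0.34) were among them. Sex-linked genes separated the genotypes, with Xist (6.41 ± 1.50) and Eif2s3y (-4.17 ± 1.27), so sex moved with genotype in every sample beside each of these groups, and the liver genes Mup20 (-4.97 ± 0.42), Cyp2d9 (-4.30 ± 0.65) and Cyp2a4 (3.32 ± 0.43) differed too. Against 2032 genes here, the count was 520 with array weights, 129 with only the compared groups in the fit and 1196 to 2941 with 1 sample left out. Quantile normalization gave 1030 higher and 1102 lower.

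Adult kidney F4/80high macrophages had 609 changed genes in the knockout, 234 higher and 375 lower (3 samples against 3). F13a1 (4.50 ± 0.46), a coagulation factor subunit, rose with Mrgpra2a (5.16 ± 0.45) and Cd300lb (3.90 ± 0.29), while the adhesion gene Vcam1 (-4.59 ± 0.46) fell with Klra2 (-4.71 ± 0.46) and Tlr12 (-4.02 ± 0.32). Of 26 tested cell cycle genes, 0 were higher, 19 lower and 7 not past the test (adjusted over the list alone 0 and 25, camera adjusted p = 2.04e-38). Bub1b (-2.47 ± 0.26), Nusap1 (-1.64 ± 0.23) and Mcm3 (-1.04 ± 0.16) were among them. Interferon-stimulated genes (34 tested) counted 0 higher, 7 lower and 27 not past the test (adjusted over the list alone 1 and 12, camera adjusted p = 6.25e-07, adjusted p = 0.286 with an estimated correlation). Oasl1 (-2.15 ± 0.34) and Mx1 (-1.78 ± 0.33) were among them. 4 of 22 tested Kupffer cell signature genes were higher, 1 lower and 17 not past the test (adjusted over the list alone 6 and 2, camera adjusted p = 4.15e-05, adjusted p = 0.0734 with an estimated correlation). C6 (2.65 ± 0.23), Clec4n (1.99 ± 0.25) and Vsig4 (2.30 ± 0.43) were among them. Of 24 tested neutrophil markers, 2 were higher, 0 lower and 22 not past the test (adjusted over the list alone 2 and 0, camera adjusted p = 0.0925). The mean level of the neutrophil list was 3.76, 3.76 and 2.82 in the 3 knockout samples, so that of replicate 3 was not raised over the wild type (2.82, 2.83 and 2.91). Against 609 genes here, the count was 361 with only the compared groups in the fit.

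Langerhans cells, the macrophage-like cells of the epidermis, changed in 4618 genes, 2839 higher and 1779 lower (3 samples against 3). The titles of the wild-type samples name GFP+ cells and those of the knockout do not. A difference of reporter or gate may thus have moved with genotype, and its effect cannot be told apart here. Retnla (6.03 ± 0.79) and the lysozyme gene Lyz1 (4.81 ± 0.52) rose with the transcription factor gene Maf (3.93 ± 0.37). Timd4 (-5.08 ± 0.40), a receptor for phosphatidylserine, fell with the epidermal genes Sprr2e (-4.34 ± 0.36) and Sprr2h (-3.91 ± 0.28). Cell cycle genes (26 tested) counted 19 higher, 0 lower and 7 not past the test (adjusted over the list alone 21 and 0, camera adjusted p = 2.16e-08, adjusted p = 0.148 with an estimated correlation). Nusap1 (1.67 ± 0.23) and Mcm6 (1.52 ± 0.22) were among them. 14 of 20 tested immediate early and heat shock genes were higher, 0 lower and 6 not past the test (adjusted over the list alone 14 and 0, camera adjusted p = 3.24e-06, adjusted p = 0.148 with an estimated correlation). Ier2 (2.07 ± 0.21) and Nr4a1 (2.40 ± 0.27) were among them. Of 16 tested keratinocyte and fibroblast markers, 8 were higher, 1 lower and 7 not past the test (adjusted over the list alone 8 and 1, camera adjusted p = 0.00578, adjusted p = 0.148 with an estimated correlation). Trp63 (3.18 ± 0.19) and Krt15 (3.26 ± 0.21) were among them. Langerhans cell signature genes (17 tested) counted 2 higher, 3 lower and 12 not past the test (adjusted over the list alone 2 and 3, camera adjusted p = 0.722). Nedd4 (2.20 ± 0.30), Ly75 (-1.95 ± 0.40) and Cdh1 (1.40 ± 0.41) were among them. The Y-linked Eif2s3y (3.92 ± 1.27) was higher in the knockout, with Xist at 7.70 and Eif2s3y at 7.57 in knockout replicate 3, so sex differed between the groups in part. Quantile normalization gave 2401 higher and 2323 lower. After median centring 1866 were higher and 4148 lower, with the median of all genes at -0.29 log2.

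In adult liver CD11bhigh macrophages 1572 genes were higher and 1293 lower in the knockout (2865 in all, 3 samples against 3). Genes of neutrophil granules led the rise, with Elane (7.36 ± 0.76), Ctsg (6.41 ± 0.72) and Mpo (6.39 ± 0.79). Vcan (-4.64 ± 0.42), the interferon-inducible Ifi205 (-5.16 ± 0.60) and Cxcl9 (-4.43 ± 0.39), and the scavenger receptor gene Msr1 (-3.92 ± 0.39) fell. 19 of 24 tested neutrophil markers were higher, 0 lower and 5 not past the test (adjusted over the list alone 21 and 0, camera adjusted p = 6.95e-24). Chil1 (5.87 ± 0.46) and Cxcr2 (4.54 ± 0.41) were among them. Of 26 tested cell cycle genes, 25 were higher, 0 lower and 1 not past the test (adjusted over the list alone 25 and 0, camera adjusted p = 3.67e-60). Kif11 (4.40 ± 0.29) and Cdk1 (4.14 ± 0.29) were among them. Interferon-stimulated genes (34 tested) counted 0 higher, 26 lower and 8 not past the test (adjusted over the list alone 0 and 32, camera adjusted p = 1.85e-19). Ifi204 (-3.60 ± 0.43) and Mx1 (-2.42 ± 0.33) were among them. 2 of 28 tested pattern recognition receptors were higher, 21 lower and 5 not past the test (adjusted over the list alone 2 and 22, camera adjusted p = 4.88e-11). Clec7a (-1.87 ± 0.21) and Clec5a (2.76 ± 0.39) were among them. Of 13 tested B cell markers, 11 were higher, 0 lower and 2 not past the test (adjusted over the list alone 11 and 0, camera adjusted p = 4.68e-07). Ms4a1 (2.98 ± 0.34) and Blnk (2.02 ± 0.30) were among them. Median centring gave 1233 higher and 2003 lower, with the median of all genes at -0.16 log2.

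Adult kidney CD11bhigh macrophages changed in 2332 genes in the knockout, 1187 higher and 1145 lower (3 samples against 3). Neutrophil granule genes rose here as well, with Camp (8.20 ± 0.99), Ngp (7.60 ± 0.84), Ltf (6.58 ± 0.65) and Lcn2 (5.73 ± 0.65). The natural killer cell genes Ncr1 (-3.93 ± 0.46), Gzma (-3.51 ± 0.46) and Gzmb (-3.36 ± 0.58) fell. Neutrophil markers (24 tested) counted 15 higher, 1 lower and 8 not past the test (adjusted over the list alone 16 and 1, camera adjusted p = 5.75e-16, adjusted p = 0.0665 with an estimated correlation). 24 of 26 tested cell cycle genes were higher, 0 lower and 2 not past the test (adjusted over the list alone 24 and 0, camera adjusted p = 1.26e-33). Uhrf1 (2.68 ± 0.31) and Nusap1 (1.77 ± 0.23) were among them. Of 19 tested T and NK cell markers, 0 were higher, 11 lower and 8 not past the test (adjusted over the list alone 0 and 11, camera adjusted p = 1.02e-08, adjusted p = 0.0884 with an estimated correlation). MHC class II genes (12 tested) counted 4 higher, 0 lower and 8 not past the test (adjusted over the list alone 4 and 0, camera adjusted p = 0.00025, adjusted p = 0.182 with an estimated correlation). H2-Ob (2.00 ± 0.37) and Ciita (1.78 ± 0.34) were among them. 0 of 19 tested kidney tubule markers were higher, 5 lower and 14 not past the test (adjusted over the list alone 0 and 9, camera adjusted p = 1.75e-05, adjusted p = 0.188 with an estimated correlation). Slc12a1 (-3.35 ± 0.57) and Umod (-3.00 ± 0.61) were among them. Tubule list means were 7.94, 6.43 and 5.65 in wild-type replicates 1, 2 and 3 and 6.15, 4.81 and 5.70 in the knockout, so wild-type replicate 1 stood apart and the others overlapped. Against 2332 genes here, the count was 893 with array weights and 143 with only the compared groups in the fit.

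At E14, microglia changed in 2442 genes in the knockout, 1420 higher and 1022 lower (3 samples against 3). Sall1 (-5.71 ± 0.34) and the fructose transporter gene Slc2a5 (-5.29 ± 0.40) fell with Il1a (-5.41 ± 0.58) and Ly86 (-5.08 ± 0.62). The neutrophil collagenase gene Mmp8 (4.89 ± 0.46) rose with Retnlg (4.61 ± 0.69) and Csta3 (5.67 ± 0.84). Of 22 tested microglia signature genes, 0 were higher, 13 lower and 9 not past the test (adjusted over the list alone 0 and 15, camera adjusted p = 1.89e-17). Tmem119 (-1.90 ± 0.27) was among them. Neutrophil markers (24 tested) counted 17 higher, 1 lower and 6 not past the test (adjusted over the list alone 23 and 1, camera adjusted p = 5.69e-16). 14 of 17 tested monocyte markers were higher, 1 lower and 2 not past the test (adjusted over the list alone 14 and 1, camera adjusted p = 1.48e-12). Gpr141 (3.06 ± 0.37) and Plac8 (2.74 ± 0.34) were among them. Of 29 tested lysosome and endocytosis genes, 1 was higher, 15 lower and 13 not past the test (adjusted over the list alone 1 and 17, camera adjusted p = 3.51e-12). Ctsh (-4.28 ± 0.35) and Ctsz (-1.35 ± 0.19) were among them. Against 2442 genes here, the count was 4427 with array weights and 3984 with only the compared groups in the fit.

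E14 Kupffer cells changed in 3933 genes in the knockout, 2255 higher and 1678 lower (3 samples against 3). The receptor tyrosine kinase gene Axl (-5.63 ± 0.39) fell with Ly86 (-5.51 ± 0.62) and Ctsh (-4.57 ± 0.35), and the early response genes Cd69 (5.54 ± 0.30), Ptgs2 (4.64 ± 0.31) and Egr1 (4.15 ± 0.34) rose. Kupffer cell signature genes (22 tested) counted 0 higher, 17 lower and 5 not past the test (adjusted over the list alone 0 and 19, camera adjusted p = 3.2e-20). C6 (-3.70 ± 0.23), Il18bp (-3.72 ± 0.28) and Clec4f (-3.32 ± 0.29) were among them. 0 of 23 tested core macrophage genes were higher, 18 lower and 5 not past the test (adjusted over the list alone 0 and 18, camera adjusted p = 6e-16). Csf1r (-1.70 ± 0.18) and C1qa (-2.85 ± 0.31) were among them. Of 20 tested immediate early and heat shock genes, 18 were higher, 0 lower and 2 not past the test (adjusted over the list alone 19 and 0, camera adjusted p = 1.01e-22). Nr4a1 (3.89 ± 0.27) and Fos (3.24 ± 0.29) were among them. The mean level of this list was 5.86 in wild type and 7.74 in the knockout. A difference in handling between the wild-type and knockout samples could also have moved these genes, and its effect cannot be told apart here. Interferon-stimulated genes (34 tested) counted 1 higher, 24 lower and 9 not past the test (adjusted over the list alone 1 and 27, camera adjusted p = 1.24e-14). Stat2 (-1.74 ± 0.18) and Oas2 (-2.23 ± 0.30) were among them. 0 of 19 tested hepatocyte markers were higher, 8 lower and 11 not past the test (adjusted over the list alone 1 and 12, camera adjusted p = 2.17e-06, adjusted p = 0.0857 with an estimated correlation). Of 14 tested erythroid markers, 0 were higher, 8 lower and 6 not past the test (adjusted over the list alone 0 and 8, camera adjusted p = 3.12e-05).

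E14 kidney F4/80high macrophages had 337 changed genes, 101 higher and 236 lower (3 knockout samples against 2 wild type). Ly86 (-4.79 ± 0.69), Ctsh (-3.58 ± 0.40), Spic (-3.16 ± 0.40) and Axl (-2.90 ± 0.43) fell, and Cxcr2 (2.12 ± 0.46), a chemokine receptor of neutrophils, rose with Stfa1 (5.22 ± 0.72) and Cxcl3 (3.18 ± 0.59). MHC class II genes (12 tested) counted 0 higher, 1 lower and 11 not past the test (adjusted over the list alone 0 and 3, camera adjusted p = 0.0117, adjusted p = 0.951 with an estimated correlation). H2-DMa (-1.73 ± 0.30) was among them. 0 of 34 tested interferon-stimulated genes were higher, 3 lower and 31 not past the test (adjusted over the list alone 1 and 5, camera adjusted p = 0.0537). Phf11b (-2.35 ± 0.38) and Zbp1 (-1.47 ± 0.36) were among them. Against 337 genes here, the count was 783 with array weights, 121 with only the compared groups in the fit and 132 to 484 with 1 sample left out.

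In E14 liver CD11bhigh macrophages 979 genes were higher and 1418 lower in the knockout (2397 in all, 3 samples against 3). The cytokine gene Il1b (3.83 ± 0.30) rose with Jun (3.69 ± 0.27) and Retnlg (4.19 ± 0.69), while the basophil protease genes Mcpt8 (-4.85 ± 0.42) and Prss34 (-3.78 ± 0.37) fell with Ms4a4c (-4.96 ± 0.57). Of 20 tested immediate early and heat shock genes, 16 were higher, 0 lower and 4 not past the test (adjusted over the list alone 16 and 0, camera adjusted p = 1.07e-25). The list rose in both gates of E14 knockout liver, and the limit on handling given for E14 Kupffer cells holds here too. MHC class II genes (12 tested) counted 0 higher, 8 lower and 4 not past the test (adjusted over the list alone 0 and 10, camera adjusted p = 8.39e-12). Ctss (-3.65 ± 0.24) and H2-DMa (-2.62 ± 0.27) were among them. 1 of 34 tested interferon-stimulated genes was higher, 23 lower and 10 not past the test (adjusted over the list alone 1 and 25, camera adjusted p = 1.29e-16). Phf11b (-3.34 ± 0.34) and Zbp1 (-3.01 ± 0.32) were among them. Of 13 tested basophil and mast cell markers, 0 were higher, 7 lower and 6 not past the test (adjusted over the list alone 0 and 7, camera adjusted p = 3.16e-07). Neutrophil markers (24 tested) counted 9 higher, 0 lower and 15 not past the test (adjusted over the list alone 9 and 0, camera adjusted p = 1.64e-06, adjusted p = 0.256 with an estimated correlation). Against 2397 genes here, the count was 4819 with array weights, 4599 with only the compared groups in the fit and 1375 to 2020 with 1 sample left out. Median centring gave 1709 higher and 774 lower, with the median of all genes at 0.16 log2.

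E14 kidney CD11bhigh macrophages changed in 2389 genes in the knockout, 1012 higher and 1377 lower (3 samples against 3). Neutrophil genes rose, with Mmp8 (5.46 ± 0.46), Ltf (5.25 ± 0.65), Ngp (5.16 ± 0.84) and Ceacam10 (5.13 ± 0.46), and the complement genes C1qb (-4.96 ± 0.46) and C1qc (-3.81 ± 0.39) fell with the chemokine gene Ccl12 (-4.38 ± 0.49). 17 of 24 tested neutrophil markers were higher, 0 lower and 7 not past the test (adjusted over the list alone 20 and 0, camera adjusted p = 2.99e-25). Of 23 tested core macrophage genes, 0 were higher, 15 lower and 8 not past the test (adjusted over the list alone 0 and 15, camera adjusted p = 6.85e-18). C1qa (-3.41 ± 0.31) was among them. Interferon-stimulated genes (34 tested) counted 0 higher, 24 lower and 10 not past the test (adjusted over the list alone 0 and 28, camera adjusted p = 4.1e-20). Dhx58 (-1.80 ± 0.22) and Zbp1 (-2.41 ± 0.32) were among them. 1 of 13 tested basophil and mast cell markers was higher, 7 lower and 5 not past the test (adjusted over the list alone 1 and 7, camera adjusted p = 0.000101, adjusted p = 0.0771 with an estimated correlation). Mcpt8 (-2.96 ± 0.42) and Cyp11a1 (-2.48 ± 0.38) were among them. Knockout replicate 3 stood apart, with list means of 9.48, 9.31 and 7.62 for neutrophil markers and 6.99, 7.29 and 8.28 for core macrophage genes in replicates 1, 2 and 3. Against 2389 genes here, the count was 815 with only the compared groups in the fit and 1546 to 2886 with 1 sample left out. Median centring gave 1391 higher and 1043 lower.

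In the yolk-sac population A1 the knockout changed 574 genes, 101 higher and 473 lower (3 samples against 3). The acute phase gene Saa3 (-5.77 ± 0.61) fell with Ccl2 (-4.08 ± 0.46) and Gzmd (-4.32 ± 0.29), and the endoderm genes Spink1 (3.79 ± 0.64) and Afp (1.92 ± 0.52) rose. Of 17 tested monocyte markers, 0 were higher, 10 lower and 7 not past the test (adjusted over the list alone 0 and 13, camera adjusted p = 1.26e-19). Itgam (-1.94 ± 0.25) and Itgal (-1.57 ± 0.22) were among them. Complement and Fc receptors (17 tested) counted 0 higher, 13 lower and 4 not past the test (adjusted over the list alone 0 and 14, camera adjusted p = 4.83e-26). Cfp (-1.82 ± 0.22) and C4b (-2.73 ± 0.38) were among them. 0 of 34 tested interferon-stimulated genes were higher, 15 lower and 19 not past the test (adjusted over the list alone 0 and 24, camera adjusted p = 4.14e-32). Phf11b (-3.14 ± 0.34) and Irf7 (-2.39 ± 0.28) were among them. Of 19 tested hepatocyte markers, 2 were higher, 0 lower and 17 not past the test (adjusted over the list alone 6 and 1, camera adjusted p = 0.00732, adjusted p = 0.287 with an estimated correlation). Against 574 genes here, the count was 1486 with array weights, 1104 with only the compared groups in the fit and 330 to 509 with 1 sample left out. Median centring gave 316 higher and 339 lower, with the median of all genes at 0.14 log2.

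Population A2 changed in 1718 genes in the knockout, 644 higher and 1074 lower (3 samples against 3). The iron exporter gene Slc40a1 (-5.78 ± 0.34), Ly86 (-6.13 ± 0.62), C1qb (-5.72 ± 0.46) and Ctss (-5.05 ± 0.24) fell, and Angpt1 (2.57 ± 0.29) and Mrgpra2a (3.02 ± 0.45) rose. Core macrophage genes (23 tested) counted 0 higher, 17 lower and 6 not past the test (adjusted over the list alone 0 and 19, camera adjusted p = 3.47e-37). Lgmn (-3.46 ± 0.25) was among them. 0 of 29 tested lysosome and endocytosis genes were higher, 23 lower and 6 not past the test (adjusted over the list alone 0 and 24, camera adjusted p = 3.68e-48). Grn (-3.07 ± 0.14) and Ctsb (-3.42 ± 0.16) were among them. Of 19 tested progenitor genes, 8 were higher, 0 lower and 11 not past the test (adjusted over the list alone 11 and 0, camera adjusted p = 6.2e-08). Meis1 (1.50 ± 0.25) and Gfi1b (2.12 ± 0.40) were among them. Interferon-stimulated genes (34 tested) counted 0 higher, 17 lower and 17 not past the test (adjusted over the list alone 0 and 22, camera adjusted p = 5.92e-16). Against 1718 genes here, the count was 3195 with array weights. Median centring gave 989 higher and 892 lower, with the median of all genes at 0.11 log2.

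**Figure D2:**
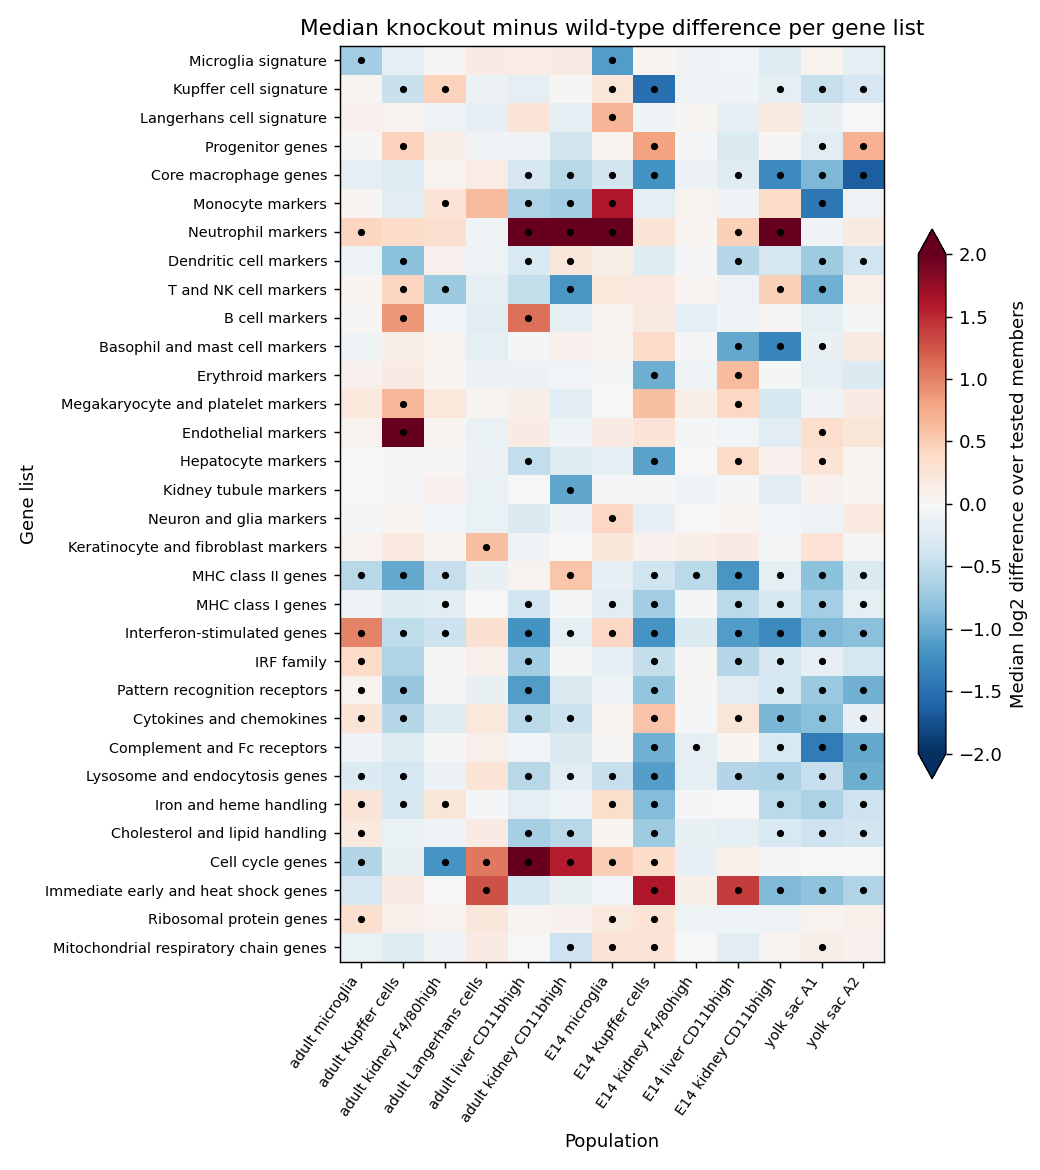
Median log2 difference, knockout minus wild type, over the tested members of each gene list (rows) in each population (columns), with a black dot where the camera adjusted p was under the threshold. Colours end at 2 log2 units, so larger medians, such as 3.93 for neutrophil markers in adult liver CD11bhigh macrophages, share the darkest shade.

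Across the 6 adult knockout comparisons, 399 genes were called higher and 345 lower in 3 or more, 744 in all, against a median of 193 and a highest value of 236 over 1000 shuffles of the gene labels. In all, 9180 genes were called in at least 1 adult comparison, and 1938 had calls in both directions in different populations. The knockout effect differed among adult microglia, Kupffer cells, kidney F4/80high macrophages and Langerhans cells in 5918 genes by the moderated F-test. Sex, and perhaps the Langerhans cell gate, enters this test. Adult and E14 microglia shared 311 higher and 402 lower genes, against 83.1 and 89 for independent lists. Adult and E14 Kupffer cells shared 160 and 341, against 101.3 and 124. E14 Kupffer cells shared more with A2, 316 and 563 against 84.9 and 105.4, so sharing was not bound to 1 tissue. The values for independent lists carry the same limit as the shuffles.

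The knockout effect in microglia differed between adults and E14 in 1794 genes, 632 with a higher and 1162 with a lower change in adults. Apoc1 (7.01 ± 0.35), Ms4a7 (6.62 ± 0.50) and Cxcl2 (5.66 ± 0.48) had the largest positive differences and Upk1b (-6.34 ± 0.37), Csta3 (-5.77 ± 1.18) and Ttr (-5.59 ± 1.20) the largest negative ones. 0 of 26 tested cell cycle genes were higher, 15 lower and 11 not past the test (adjusted over the list alone 0 and 20, camera adjusted p = 1.2e-11, adjusted p = 0.125 with an estimated correlation). Of 24 tested neutrophil markers, 1 was higher, 10 lower and 13 not past the test (adjusted over the list alone 2 and 14, camera adjusted p = 0.000111, adjusted p = 0.367 with an estimated correlation). Against 1794 genes here, the count was 2884 with array weights. Quantile normalization gave 840 higher and 937 lower.

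In Kupffer cells the same test of the difference called 2793 genes, 1006 with a higher and 1787 with a lower change in adults, where sex moved with genotype. Xist (7.60 ± 2.13), Axl (4.44 ± 0.55) and Aqp1 (4.27 ± 0.55) had the largest positive differences and Mup20 (-5.46 ± 0.59), Gbp2b (-5.16 ± 0.51) and Cd69 (-5.13 ± 0.43) the largest negative ones. Kupffer cell signature genes (22 tested) counted 11 higher, 0 lower and 11 not past the test (adjusted over the list alone 12 and 0, camera adjusted p = 2.03e-10). 0 of 20 tested immediate early and heat shock genes were higher, 16 lower and 4 not past the test (adjusted over the list alone 0 and 17, camera adjusted p = 1.28e-13). The limit on handling given for E14 knockout liver holds for this difference too. Of 18 tested endothelial markers, 11 were higher, 0 lower and 7 not past the test (adjusted over the list alone 13 and 1, camera adjusted p = 3.1e-10). Against 2793 genes here, the count was 1091 with only the compared groups in the fit. Quantile normalization gave 1361 higher and 1422 lower.

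For kidney F4/80high macrophages the difference was called in 177 genes, 99 higher and 78 lower in adults. F13a1 (4.42 ± 0.70), Clec2i (3.91 ± 0.63) and Ly86 (3.90 ± 0.93) had the largest positive differences and Stfa1 (-5.28 ± 0.97), Klra2 (-4.92 ± 0.68) and Pde7b (-3.98 ± 0.49) the largest negative ones. Cell cycle genes (26 tested) counted 0 higher, 4 lower and 22 not past the test (adjusted over the list alone 0 and 17, camera adjusted p = 1.9e-18). Against 177 genes here, the count was 360 with array weights, 79 with only the compared groups in the fit and 65 to 232 with 1 sample left out.

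Between A2 and A1 the knockout effect differed in 283 genes, 104 with a higher and 179 with a lower change in A2. Saa3 (6.36 ± 0.87), Slpi (5.23 ± 0.75) and Gzmd (4.35 ± 0.41) had the largest positive differences and Lyve1 (-4.95 ± 0.76), Slc40a1 (-4.41 ± 0.48) and Hbb-bh1 (-4.23 ± 1.05) the largest negative ones. 7 of 19 tested progenitor genes were higher, 0 lower and 12 not past the test (adjusted over the list alone 13 and 0, camera adjusted p = 1.62e-15). Of 29 tested lysosome and endocytosis genes, 0 were higher, 7 lower and 22 not past the test (adjusted over the list alone 0 and 16, camera adjusted p = 1.27e-20). Against 283 genes here, the count was 860 with array weights and 529 with only the compared groups in the fit.

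The wild-type samples were then compared along development. Against E8 erythro-myeloid progenitors, A1 had 2189 genes higher and 1690 lower (3879 in all, 3 samples against 3). The myeloid genes Mpo (7.10 ± 0.79), Tyrobp (6.71 ± 0.11), Lyz2 (6.22 ± 0.19) and Ctss (6.03 ± 0.24) rose, and the erythroid membrane gene Slc4a1 (-5.62 ± 0.38) fell with Hbq1b (-5.57 ± 0.38). Core macrophage genes (23 tested) counted 18 higher, 0 lower and 5 not past the test (adjusted over the list alone 18 and 0, camera adjusted p = 1.35e-22). 22 of 28 tested pattern recognition receptors were higher, 0 lower and 6 not past the test (adjusted over the list alone 24 and 0, camera adjusted p = 2.34e-24). Of 14 tested erythroid markers, 0 were higher, 14 lower and 0 not past the test (adjusted over the list alone 0 and 14, camera adjusted p = 6.79e-23). Trim10 (-4.98 ± 0.27) and Sptb (-5.00 ± 0.28) were among them. Median centring gave 5944 genes against 3879 here, 1677 higher and 4267 lower, with the median of all genes at -0.32 log2.

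A2 had 969 genes higher and 974 lower than A1 (1943 in all, 3 samples against 3). The macrophage mannose receptor gene Mrc1 (4.36 ± 0.38) and the microglia genes P2ry12 (3.85 ± 0.38) and Fcrls (4.33 ± 0.38) rose with Slc40a1 (4.41 ± 0.34), and Saa3 (-5.99 ± 0.61) and Gata2 (-4.64 ± 0.39) fell. Core macrophage genes (23 tested) counted 19 higher, 0 lower and 4 not past the test (adjusted over the list alone 20 and 0, camera adjusted p = 6.16e-34). 0 of 19 tested progenitor genes were higher, 16 lower and 3 not past the test (adjusted over the list alone 0 and 16, camera adjusted p = 1.92e-30). Gata1 (-3.66 ± 0.27) and Angpt1 (-3.66 ± 0.29) were among them. Of 22 tested microglia signature genes, 9 were higher, 0 lower and 13 not past the test (adjusted over the list alone 12 and 0, camera adjusted p = 6.26e-08). B cell markers (13 tested) counted 0 higher, 9 lower and 4 not past the test (adjusted over the list alone 0 and 11, camera adjusted p = 2.08e-12). Against 1943 genes here, the count was 3294 with array weights. Median centring gave 1371 higher and 698 lower, with the median of all genes at 0.11 log2.

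From A2 to E14 microglia 2396 genes were higher and 2598 lower (4994 in all, 3 samples against 3). Sall1 (6.34 ± 0.34) rose with Siglech (5.35 ± 0.41) and Sparc (5.31 ± 0.35), and the embryonic globin gene Hbb-bh1 (-5.14 ± 0.74) fell with Plac8 (-3.43 ± 0.34). 21 of 22 tested microglia signature genes were higher, 0 lower and 1 not past the test (adjusted over the list alone 21 and 0, camera adjusted p = 1.12e-33). Of 26 tested cell cycle genes, 0 were higher, 23 lower and 3 not past the test (adjusted over the list alone 0 and 26, camera adjusted p = 9.44e-12). Neuron and glia markers (14 tested) counted 6 higher, 0 lower and 8 not past the test (adjusted over the list alone 6 and 0, camera adjusted p = 0.000152). Median centring gave 1877 higher and 3289 lower, with the median of all genes at -0.14 log2.

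E14 Kupffer cells differed from A2 in 4371 genes, 1971 higher and 2400 lower (3 samples against 3). The macrophage genes Cd5l (8.41 ± 0.38), Spic (7.22 ± 0.36) and Marco (6.70 ± 0.30) rose with the hepatocyte gene Alb (7.59 ± 0.42). 19 of 22 tested Kupffer cell signature genes were higher, 0 lower and 3 not past the test (adjusted over the list alone 19 and 0, camera adjusted p = 1.76e-34). Of 19 tested hepatocyte markers, 16 were higher, 0 lower and 3 not past the test (adjusted over the list alone 16 and 0, camera adjusted p = 2.75e-28). Erythroid markers (14 tested) counted 11 higher, 0 lower and 3 not past the test (adjusted over the list alone 11 and 0, camera adjusted p = 2.97e-27). 16 of 18 tested genes of iron and heme handling were higher, 1 lower and 1 not past the test (adjusted over the list alone 16 and 1, camera adjusted p = 5.48e-16). Median centring gave 1588 higher and 3691 lower, with the median of all genes at -0.21 log2.

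E14 kidney F4/80high macrophages differed from A2 in 3104 genes, 1691 higher and 1413 lower (2 samples against 3). The inflammatory cytokine genes Cxcl2 (7.53 ± 0.38), Il1b (7.31 ± 0.33) and Cxcl10 (6.56 ± 0.56) rose, and Stfa1 (-7.12 ± 0.72) and Cd34 (-4.66 ± 0.34) fell. Of 20 tested immediate early and heat shock genes, 17 were higher, 0 lower and 3 not past the test (adjusted over the list alone 18 and 0, camera adjusted p = 5.26e-36). Cytokines and chemokines genes (32 tested) counted 22 higher, 0 lower and 10 not past the test (adjusted over the list alone 24 and 0, camera adjusted p = 6.64e-23). Against 3104 genes here, the count was 1850 to 2597 with 1 sample left out. Median centring gave 1405 higher and 1916 lower, with the median of all genes at -0.11 log2.

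Adult microglia had 1143 genes higher and 1993 lower than E14 microglia (3136 in all, 3 samples against 3). Upk1b (6.25 ± 0.26) and the early response genes Fos (5.45 ± 0.29) and Egr1 (4.55 ± 0.34) rose, and Apoc1 (-6.56 ± 0.25), Pf4 (-5.70 ± 0.58) and Mrc1 (-4.84 ± 0.38) fell. 0 of 26 tested cell cycle genes were higher, 25 lower and 1 not past the test (adjusted over the list alone 0 and 25, camera adjusted p = 1.4e-47). Of 20 tested immediate early and heat shock genes, 17 were higher, 0 lower and 3 not past the test (adjusted over the list alone 18 and 0, camera adjusted p = 4.78e-34). Microglia signature genes (22 tested) counted 10 higher, 0 lower and 12 not past the test (adjusted over the list alone 12 and 0, camera adjusted p = 1.65e-06). Median centring gave 1629 higher and 1505 lower, with the median of all genes at 0.12 log2.

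Adult Kupffer cells differed from those at E14 in 5135 genes, 2010 higher and 3125 lower (3 samples against 3). Sex moved with stage in part, since Xist was 3.23, 2.71 and 3.88 in adults and 9.71, 5.76 and 9.21 at E14. The MHC class II genes H2-Ab1 (7.45 ± 0.34) and H2-Aa (7.01 ± 0.36) rose with Cxcl13 (7.21 ± 0.39) and the hepatocyte gene Mup3 (8.27 ± 0.55), and the globin gene Hbb-y (-7.53 ± 0.83) and the fetal liver gene Afp (-7.50 ± 0.52) fell. 0 of 14 tested erythroid markers were higher, 14 lower and 0 not past the test (adjusted over the list alone 0 and 14, camera adjusted p = 6.27e-29). Of 26 tested cell cycle genes, 0 were higher, 26 lower and 0 not past the test (adjusted over the list alone 0 and 26, camera adjusted p = 7.36e-38). Genes stimulated by interferon (34 tested) counted 28 higher, 1 lower and 5 not past the test (adjusted over the list alone 30 and 1, camera adjusted p = 1.89e-15). 13 of 19 tested hepatocyte markers were higher, 1 lower and 5 not past the test (adjusted over the list alone 14 and 1, camera adjusted p = 1.45e-08).

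Adult kidney F4/80high macrophages differed from those at E14 in 4824 genes, 2093 higher and 2731 lower (3 samples against 2). The MHC class II genes H2-Ab1 (8.47 ± 0.38), H2-Aa (8.05 ± 0.40) and H2-Eb1 (7.17 ± 0.38) rose with the kidney tubule gene Kap (8.31 ± 0.32), and Lyve1 (-6.65 ± 0.60) and F13a1 (-4.50 ± 0.52) fell. Of 12 tested MHC class II genes, 9 were higher, 1 lower and 2 not past the test (adjusted over the list alone 10 and 1, camera adjusted p = 4.37e-12). Kidney tubule markers (19 tested) counted 13 higher, 2 lower and 4 not past the test (adjusted over the list alone 13 and 2, camera adjusted p = 3.35e-11). 0 of 26 tested cell cycle genes were higher, 25 lower and 1 not past the test (adjusted over the list alone 0 and 26, camera adjusted p = 8.51e-19). Median centring gave 1744 higher and 3273 lower (median of all genes -0.16 log2).

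Each adult resident population was compared with the mean of the other 3 (3 samples against 9). Sex moved with tissue, since Xist ran from 2.58 to 3.88 in Kupffer cells and kidney F4/80high macrophages and from 9.77 to 10.30 in Langerhans cells, and in microglia it was 2.99, 10.17 and 10.36. In microglia 3497 genes were higher and 3542 lower (7039 in all). Sall1 (6.48 ± 0.28), Slc2a5 (6.60 ± 0.32) and Siglech (6.18 ± 0.33) were higher, and the MHC class II genes H2-Eb1 (-7.07 ± 0.27) and H2-Aa (-6.91 ± 0.29) and the cytokine gene Il1b (-6.51 ± 0.24) lower. Of 22 tested microglia signature genes, 22 were higher, 0 lower and 0 not past the test (adjusted over the list alone 22 and 0, camera adjusted p = 1.89e-37). Genes of cholesterol and lipid handling (21 tested) counted 2 higher, 17 lower and 2 not past the test (adjusted over the list alone 2 and 17, camera adjusted p = 4.58e-09).

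In Kupffer cells 2725 genes were higher and 3950 lower (6675 in all). The complement receptor gene Vsig4 (9.19 ± 0.35) and Cd5l (8.62 ± 0.31) were higher, as were the hepatocyte genes Alb (8.87 ± 0.34) and Fabp1 (8.48 ± 0.25). 21 of 22 tested Kupffer cell signature genes were higher, 0 lower and 1 not past the test (adjusted over the list alone 21 and 0, camera adjusted p = 4.58e-40). Of 19 tested hepatocyte markers, 18 were higher, 0 lower and 1 not past the test (adjusted over the list alone 18 and 0, camera adjusted p = 2.77e-35). Genes of iron and heme handling (18 tested) counted 16 higher, 1 lower and 1 not past the test (adjusted over the list alone 16 and 1, camera adjusted p = 5.31e-18). Quantile normalization gave 2859 higher and 3957 lower, with the median of all genes at -0.10 log2. After median centring 2467 were higher and 4458 lower, with the median of all genes at -0.15 log2.

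Kidney F4/80high macrophages had 3049 genes higher and 2110 lower (5159 in all). The interferon beta gene Ifnb1 (7.79 ± 0.60) and Mmp13 (5.85 ± 0.33) were higher, with the tubule genes Kap (8.28 ± 0.23) and Klk1 (7.15 ± 0.48). 33 of 34 tested interferon-stimulated genes were higher, 0 lower and 1 not past the test (adjusted over the list alone 33 and 0, camera adjusted p = 4.16e-29). The list mean, 7.42, was close to that of Kupffer cells (7.33), with 4.97 in microglia and 3.86 in Langerhans cells. Of 19 tested kidney tubule markers, 15 were higher, 0 lower and 4 not past the test (adjusted over the list alone 15 and 0, camera adjusted p = 2.9e-12). Median centring gave 2001 higher and 4438 lower, with the median of all genes at -0.24 log2.

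Langerhans cells had 4370 genes higher and 4664 lower (9034 in all). The langerin gene Cd207 (7.43 ± 0.20) was higher with Cldn1 (7.52 ± 0.40) and the epidermal gene Krtdap (7.80 ± 0.27), and Fcgr1 (-6.73 ± 0.21) and Tlr13 (-6.65 ± 0.24) were lower. Langerhans cell signature genes (17 tested) counted 15 higher, 1 lower and 1 not past the test (adjusted over the list alone 15 and 1, camera adjusted p = 4.96e-10). 0 of 23 tested core macrophage genes were higher, 22 lower and 1 not past the test (adjusted over the list alone 0 and 22, camera adjusted p = 1.44e-18). Of 16 tested keratinocyte and fibroblast markers, 11 were higher, 1 lower and 4 not past the test (adjusted over the list alone 11 and 1, camera adjusted p = 2.55e-08). Median centring gave 6118 higher and 3525 lower, with the median of all genes at 0.22 log2.

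**Figure D3:**
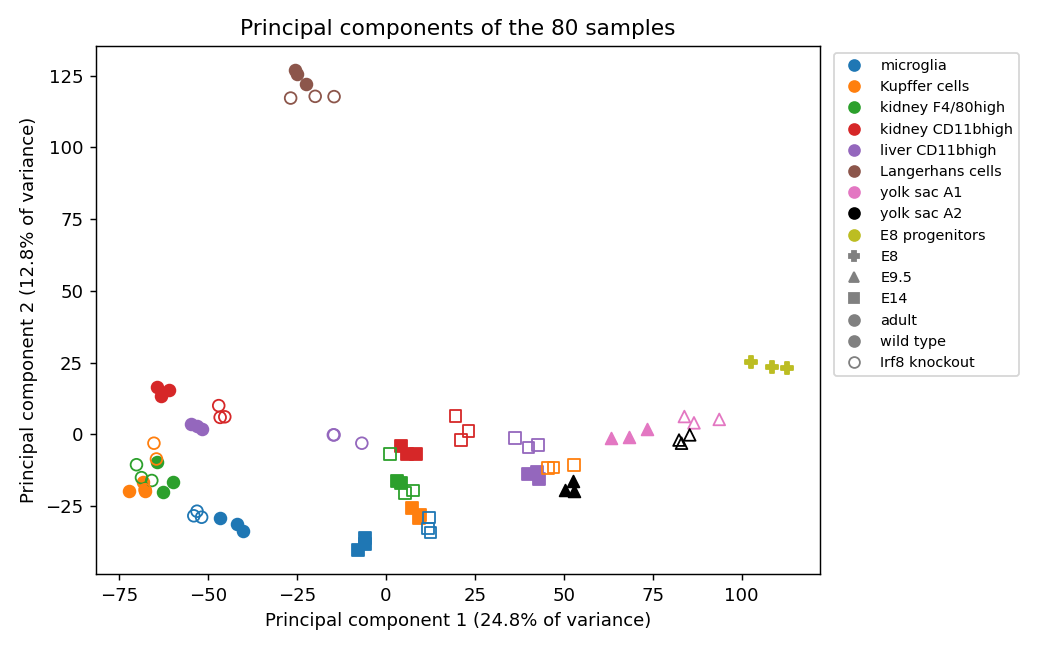
First and second principal components of the 80 samples, with 24.8% and 12.8% of the variance, coloured by population, shaped by stage, filled for wild type and open for knockout. Samples of a group lie near each other, and the A2 knockout samples lie beyond the wild-type A1 samples along the first component.

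The last comparisons set the CD11bhigh gate against the resident macrophages of the same organ, in wild type. In adult liver 2612 genes were higher and 2178 lower in CD11bhigh macrophages (4790 in all, 3 samples against 3). Retnlg (7.48 ± 0.69), Chil3 (6.81 ± 0.69) and Ace (5.48 ± 0.40) were higher, and Cxcl13 (-7.58 ± 0.39), Cd5l (-7.40 ± 0.38) and Vsig4 (-6.91 ± 0.43) lower. Monocyte markers (17 tested) counted 13 higher, 0 lower and 4 not past the test (adjusted over the list alone 13 and 0, camera adjusted p = 1.05e-14). 1 of 22 tested Kupffer cell signature genes was higher, 21 lower and 0 not past the test (adjusted over the list alone 1 and 21, camera adjusted p = 6.67e-35). Of 24 tested neutrophil markers, 14 were higher, 0 lower and 10 not past the test (adjusted over the list alone 16 and 0, camera adjusted p = 8.31e-07, adjusted p = 0.208 with an estimated correlation). Hepatocyte markers (19 tested) counted 0 higher, 16 lower and 3 not past the test (adjusted over the list alone 0 and 17, camera adjusted p = 2.08e-21). 1 of 18 tested endothelial markers was higher, 16 lower and 1 not past the test (adjusted over the list alone 1 and 17, camera adjusted p = 9.67e-15). Median centring gave 3479 higher and 1796 lower (median of all genes 0.15 log2).

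In adult kidney 1560 genes were higher and 2470 lower in CD11bhigh macrophages (4030 in all, 3 samples against 3). The fibronectin gene Fn1 (6.46 ± 0.38) was higher with Ccl17 (6.47 ± 0.53) and Chil3 (6.03 ± 0.69), and Mmp13 (-5.95 ± 0.40) and Stab1 (-5.25 ± 0.30) were lower. Of 17 tested monocyte markers, 16 were higher, 0 lower and 1 not past the test (adjusted over the list alone 16 and 0, camera adjusted p = 3.83e-30). Core macrophage genes (23 tested) counted 0 higher, 18 lower and 5 not past the test (adjusted over the list alone 0 and 19, camera adjusted p = 1.87e-15). 10 of 19 tested kidney tubule markers were higher, 0 lower and 9 not past the test (adjusted over the list alone 11 and 0, camera adjusted p = 1.16e-05, adjusted p = 0.193 with an estimated correlation). Replicate 1 had the highest tubule list mean in both gates, with 7.94, 6.43 and 5.65 in CD11bhigh and 6.38, 4.56 and 5.30 in F4/80high macrophages. Against 4030 genes here, the count was 1387 with only the compared groups in the fit. Median centring gave 2250 higher and 1815 lower (median of all genes 0.12 log2).

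At E14, liver CD11bhigh macrophages had 2293 genes higher and 1908 lower than Kupffer cells (4201 in all, 3 samples against 3). The neutrophil granule genes Ltf (6.31 ± 0.65), Camp (6.03 ± 0.99) and Lcn2 (5.68 ± 0.65) were higher, and Cd5l (-7.62 ± 0.38) and Timd4 (-6.95 ± 0.40) lower. Of 24 tested neutrophil markers, 21 were higher, 0 lower and 3 not past the test (adjusted over the list alone 22 and 0, camera adjusted p = 1.21e-17). Kupffer cell signature genes (22 tested) counted 1 higher, 19 lower and 2 not past the test (adjusted over the list alone 1 and 19, camera adjusted p = 2.1e-39). 0 of 14 tested erythroid markers were higher, 14 lower and 0 not past the test (adjusted over the list alone 0 and 14, camera adjusted p = 4.88e-20).

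E14 kidney CD11bhigh macrophages had 463 genes higher and 531 lower than F4/80high macrophages (994 in all, 3 samples against 2). The granulocyte genes S100a8 (7.68 ± 1.27) and Prg2 (7.89 ± 1.07) were higher, and Lyve1 (-5.85 ± 0.60) and Folr2 (-4.61 ± 0.49) lower. Of 13 tested basophil and mast cell markers, 10 were higher, 0 lower and 3 not past the test (adjusted over the list alone 10 and 0, camera adjusted p = 4.66e-21). Neutrophil markers (24 tested) counted 13 higher, 0 lower and 11 not past the test (adjusted over the list alone 17 and 0, camera adjusted p = 3.43e-20). 9 of 17 tested monocyte markers were higher, 0 lower and 8 not past the test (adjusted over the list alone 11 and 0, camera adjusted p = 1.01e-20). Against 994 genes here, the count was 1553 with array weights and 480 to 814 with 1 sample left out.

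**Figure D4:**
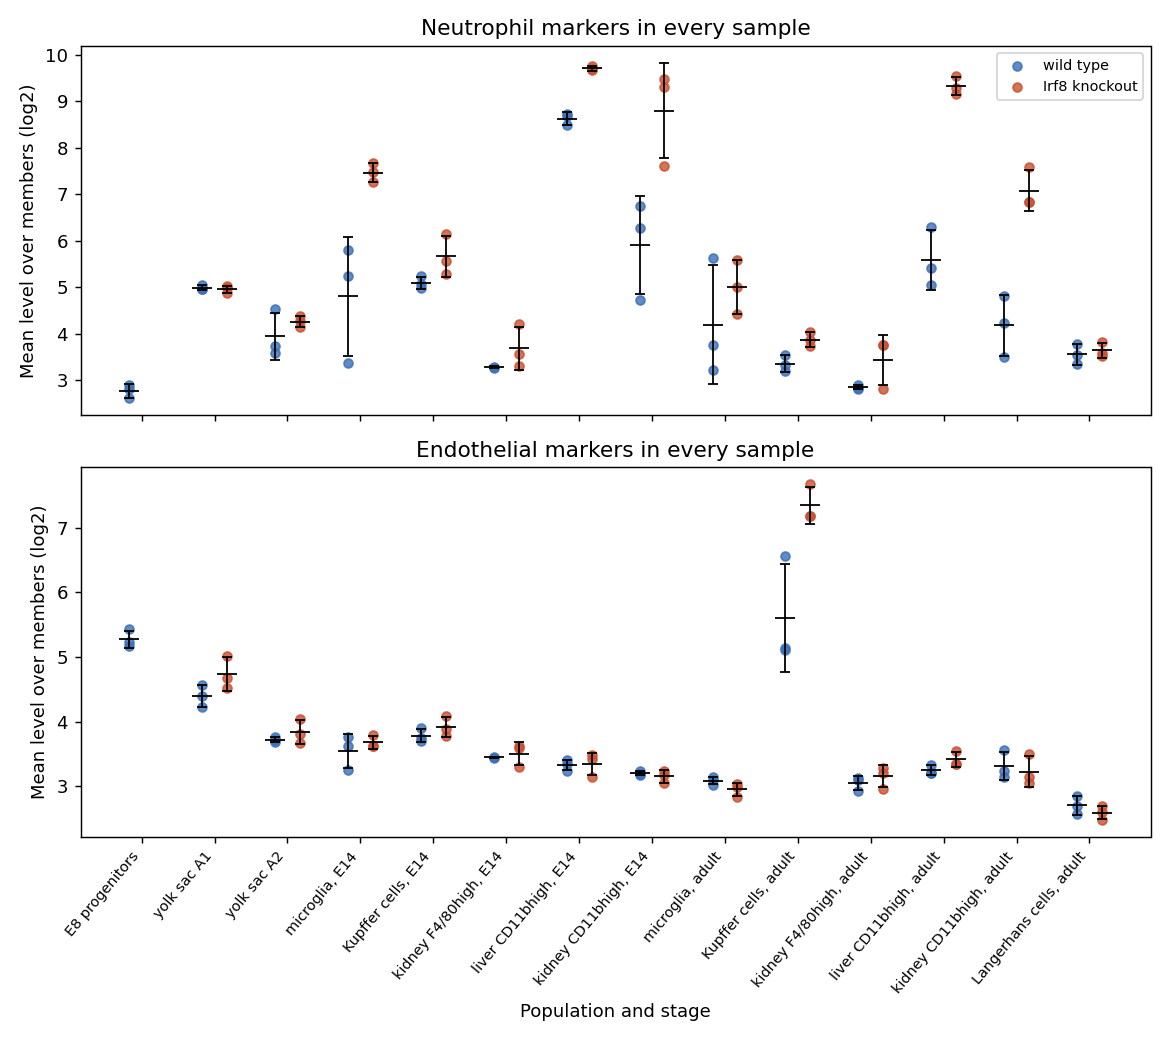
Mean log2 level over the neutrophil marker list (top) and the endothelial marker list (bottom) in every sample by population and stage, wild type in blue and knockout in red, with group mean and SD. Adult Kupffer cells show the endothelial shift, with a median of 1.99 log2 over the list.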

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

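All tests of this part were chosen only after the result was seen. The count of the second marker lists without genes already named by size, the count with an estimated correlation, the place of each sample between the genotypes and the comparison of the neutrophil list with the lists present in wild type, with its bound of 1 log2 above the floor, were added after the first counts.

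Irf8 transcript was not lower in the knockout in 4 populations, and was called lower in 4 of 13, in 1 with overlapping samples. A wrong genotype label on single samples could have done this, so each sample was placed, over genes called without it, on a line from 0 for its own group to 1 for the other genotype. In adult microglia, adult kidney F4/80high macrophages and A2, 0 of 18 samples lay nearer to the other genotype (highest 0.249), so this explanation did not hold there. In E14 kidney F4/80high macrophages 1 of 5 did, knockout replicate 3 (0.602), and without it Irf8 was 0.40 ± 0.31 log2 above the wild type, so a wrong label stays open there. Array probes outside the deleted part would leave the level free to be lower, equal or higher, and with 4 populations called lower this stays open too.

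Neutrophil markers rose by a list mean of 3.75, 2.90 and 2.88 log2 in the knockout in adult liver, adult kidney (camera adjusted p = 0.0665 with an estimated correlation) and E14 kidney CD11bhigh macrophages and by 2.66 in E14 microglia, the 4 weighed here, and by 1.08 in E14 liver CD11bhigh macrophages. A lower share of the main cell type in the 3 CD11bhigh populations would raise markers of all other cell types alike. The neutrophil list moved away from 6 of 6 lists at least 1 log2 above the floor in wild type. Differences were 3.01 to 4.34 log2 (largest adjusted p = 0.0222), monocyte and dendritic lists left out. Those lists may respond to the knockout too, so a lower share stays open. Below that bound B cell markers rose too in adult liver (by 1.25) and T and NK cell markers in E14 kidney (by 0.80), and by camera at least 1 other list was called lower in 3 of 3 populations with the preset correlation but in 0 with an estimated one. In E14 microglia, 0 such lists lay 1 log2 above the floor of 3.041 (the closest, of megakaryocytes and platelets, at 4.02). Monocyte markers rose too, so a lower share stays open here too. Cells of the neutrophil lineage in the gate would raise a second neutrophil list, and 12, 6, 13 and 15 of its 18 genes were called higher in adult liver CD11bhigh, adult kidney CD11bhigh, E14 microglia and E14 kidney CD11bhigh (10, 4, 9 and 11 of 14 without genes already named), so with the lowest values of 6 and 4 this may or may not hold.

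Endothelial markers were higher in knockout adult Kupffer cells. Endothelial cells in the sorted fraction would raise a second endothelial list, and 14 of its 16 genes were called higher, or 13 of 15 without a gene already named. This is consistent with endothelial cells in the fraction, which the array cannot tell from expression by the Kupffer cells. The sex of the animals may also count, because the lowest Xist of the knockout samples lay 5.65 log2 above the highest of the wild type. Genotype and sex separated these 6 samples in the same way, so their effects cannot be parted here.

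The knockout effect differed between adult and E14 microglia in 1794 genes, with Apoc1 (7.01), Ms4a7 (6.62), Cxcl2 (5.66), Upk1b (-6.34), Csta3 (-5.77) and Ttr (-5.59). Between adult and E14 Kupffer cells it differed in 2793 genes, with Xist (7.60), Axl (4.44), Aqp1 (4.27), Mup20 (-5.46), Gbp2b (-5.16) and Cd69 (-5.13). For kidney F4/80high macrophages it differed in 177 genes, with F13a1 (4.42), Clec2i (3.91), Ly86 (3.90), Stfa1 (-5.28), Klra2 (-4.92) and Pde7b (-3.98). For A2 and A1 it differed in 283 genes, with Saa3 (6.36), Slpi (5.23), Gzmd (4.35), Lyve1 (-4.95), Slc40a1 (-4.41) and Hbb-bh1 (-4.23). Among the 4 adult resident populations it differed in 5918 genes, sex not separated.

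Grouping by chance was tested by other splits, and with 3 samples against 3 the splits were too few (10), only 1 of which, the labelled one, gave as many genes. The highest other count stood against the labelled one in the knockout comparisons at adult microglia 28 against 2490, adult Kupffer cells 1434 against 2032, adult kidney F4/80high 57 against 609, adult Langerhans cells 23 against 4618, adult liver CD11bhigh 9 against 2865, adult kidney CD11bhigh 1231 against 2332, E14 microglia 6 against 2442, E14 Kupffer cells 6 against 3933, E14 liver CD11bhigh 0 against 2397, E14 kidney CD11bhigh 793 against 2389, yolk sac A1 40 against 574, yolk sac A2 3 against 1718. In the other comparisons of 3 against 3 it stood at A1 against E8 erythro-myeloid progenitors 26 against 3879, A2 against A1 3 against 1943, E14 microglia against A2 7 against 4994, E14 Kupffer cells against A2 2 against 4371, adult against E14 microglia 49 against 3136, adult against E14 Kupffer cells 91 against 5135, CD11bhigh against Kupffer cells, adult liver 175 against 4790, CD11bhigh against F4/80high, adult kidney 1269 against 4030, CD11bhigh against Kupffer cells, E14 liver 1 against 4201.

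Of 100 splits, the number with as many genes as the labels, the labelled one included, was 1 (highest other 4764 against 7039) for adult microglia, 1 (highest other 5795 against 6675) for adult Kupffer cells, 3 (highest other 5860 against 5159) for adult kidney F4/80high macrophages, 1 (highest other 8446 against 9034) for adult Langerhans cells in the comparison of tissues. For the differences of effects it was 2 (highest other 2946 against 1794) in microglia, 5 (highest other 3241 against 2793) in Kupffer cells and 13 (highest other 2094 against 283) between A2 and A1. Splits that kept the labels of 1 population carried its own knockout effect, such as the 1718 genes of A2. Counts above the labelled one point to that structure, so whether chance grouped the samples stays open for all 3. For the F-test it was 1 (highest other 3942 against 5918), and for genes shared by 3 or more adult comparisons 1 (highest other 8 against 744).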

How the results depend on the processing

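All these settings were fixed before the data were seen, other than the run without genes on chromosomes X and Y. Low signal over background limits what can be said of dim genes, since values near the floor of 3.041 lie near the level of genes with no transcript. Quantile normalization, other floors, every probe on its own, the separate array runs of the A2 knockout and the run without the 576 genes on chromosomes X and Y moved no count by as much as 1.5 times. Of the list tests, 249 lost their call with an estimated correlation and 32 lost and 95 gained it with fry. Lists lost a call 157 times and gained it 147 times over all fits with 1 sample left out, 47 and 8 times with the stricter floor, 3 and 39 with no floor, 17 and 38 with own groups (a fit of only the compared groups), 18 and 41 with the block, 17 and 7 with array weights, 17 and 19 with median centring and 8 and 13 with quantile normalization. Calls of named genes were lost 42 times over all fits with 1 sample left out, 15 times with own groups, 11 with the block, 4 with array weights and 1 with no floor. With A1 knockout replicate 3 left out, the B cell markers in A1 turned direction (camera adjusted p = 0.0131, range 0.00463 to 0.746 with 1 sample left out). The cause was not tested.

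In the knockout comparisons these counts of called genes moved by over 1.5 times, with the count of the planned fit in brackets. Adult Kupffer cells (2032), 520 with array weights, 129 with own groups and 1196 to 2941 with 1 sample left out. Adult kidney F4/80high (609), 361 with own groups. Adult kidney CD11bhigh (2332), 893 with array weights and 143 with own groups. E14 microglia (2442), 4427 with array weights and 3984 with own groups. E14 kidney F4/80high (337), 783 with array weights, 121 with own groups and 132 to 484 with 1 sample left out. E14 liver CD11bhigh (2397), 4819 with array weights, 4599 with own groups and 1375 to 2020 with 1 sample left out. E14 kidney CD11bhigh (2389), 815 with own groups and 1546 to 2886 with 1 sample left out. Yolk sac A1 (574), 1486 with array weights, 1104 with own groups and 330 to 509 with 1 sample left out. Yolk sac A2 (1718), 3195 with array weights.

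In the other comparisons the counts moved in the same way. A1 against E8 erythro-myeloid progenitors (3879), 5944 with median centring. A2 against A1 (1943), 3294 with array weights. E14 kidney F4/80high against A2 (3104), 1850 to 2597 with 1 sample left out. CD11bhigh against F4/80high, adult kidney (4030), 1387 with own groups. CD11bhigh against F4/80high, E14 kidney (994), 1553 with array weights and 480 to 814 with 1 sample left out. The difference of effects, adult minus E14 microglia (1794), 2884 with array weights. The difference of effects, adult minus E14 Kupffer cells (2793), 1091 with own groups. The difference of effects, adult minus E14 kidney F4/80high (177), 360 with array weights, 79 with own groups and 65 to 232 with 1 sample left out. The difference of effects, A2 minus A1 (283), 860 with array weights and 529 with own groups.

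With the replicate number as a replicate block and only the compared groups in the fit, the counts that moved were 70 in adult Kupffer cells, 160 in adult kidney F4/80high, 50 in adult kidney CD11bhigh, 3737 in E14 microglia, 938 in E14 kidney F4/80high, 4592 in E14 liver CD11bhigh, 987 in E14 kidney CD11bhigh, 1400 in CD11bhigh against F4/80high, adult kidney, 996 in the difference of effects, adult minus E14 Kupffer cells, 54 in the difference of effects, adult minus E14 kidney F4/80high, 480 in the difference of effects, A2 minus A1. The block moved no other count by as much. The labels do not say that equal numbers share animals, and in no comparison was every correlation of same-numbered samples above 0.1 (highest 0.386, adult kidney gates, replicate 1), so the planned fits are unpaired. Xist nevertheless followed the number between the gates of E14 liver in both genotypes and of E14 knockout kidney, but not in every pair of E14 wild-type kidney (3.28 and 6.01 in the last). Wild-type E14 liver had 9.71, 5.76 and 9.21 in Kupffer cells and 9.71, 5.92 and 8.82 in CD11bhigh macrophages, so shared animals or pools are not excluded. In adult microglia every sample correlated best with its own number, a hint from the data and not from the design.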

Other observations

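Groups of genes not described above moved in several knockout comparisons. In adult microglia, 6 of 15 tested ribosomal protein genes were higher, 0 lower and 9 not past the test (adjusted over the list alone 7 and 1, camera adjusted p = 6.53e-05, adjusted p = 0.108 with an estimated correlation). Rps18 (0.57 ± 0.08) and Rps19 (0.67 ± 0.10) were among them. In E14 Kupffer cells, of 17 tested complement and Fc receptors, 2 were higher, 11 lower and 4 not past the test (adjusted over the list alone 3 and 12, camera adjusted p = 5.65e-07). C1qa (-2.85 ± 0.31) and Cfp (-1.77 ± 0.22) were among them. In A1, pattern recognition receptors (28 tested) counted 0 higher, 8 lower and 20 not past the test (adjusted over the list alone 0 and 14, camera adjusted p = 1.32e-11). Clec7a (-1.94 ± 0.21) and Tlr13 (-2.62 ± 0.30) were among them.

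A hypothesis written before its test was seen was that genes linked to Irf8 on its chromosome were carried along with the knockout allele. It could have made genes near Irf8 change together in 3 or more adult comparisons, and 4 of 100 neighbours did so (4%), Gins2, Aprt, Trappc2l and Cbfa2t3, against 736 of 16973 genes elsewhere (4.34%, two-sided Fisher exact p = 1). The data did not support it.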
